A study of Mus musculus with 6 samples.

How the data were processed

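Expression was measured in As4.1 mouse cells treated with vehicle, hydrogen peroxide or an interleukin, with 2 separate cultures per group per the series description, on 6 Affymetrix mouse genome arrays. The labels do not name the interleukin, the doses or the times. The deposited values are intensities, namely MAS5 signals per probe set on a linear scale, as the authors made them per the submitters' processing notes, and the version of MAS5 is not given in the sources used here. On every array the mean after trimming 2% at each end was 1500.01, all values were above 0 and none was missing. Detection calls and scanner images were not used here. The median signal was 192.2 to 232.3 per array, and the lower quartile was 69.2 on interleukin array 2 and 48 to 54.1 on the others.

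Signals were log2 transformed with no pseudocount. Of 45101 probe sets 64 controls were left out, and the 22519 whose mean log2 signal lay at or above the median were tested, which kept geometric mean signals from 193.7 upward with a median of 1514. Gene symbols came from the array annotation, updated through the gene identifiers of a RefSeq gene table, in which 34754 of the 34958 probe sets with 1 symbol were matched. Another 932 had several symbols and 9211 had none listed. A gene was represented by its probe set of highest mean log2 signal, giving 10892 genes. No probe set was annotated to Ren1 or Ren2, and renin is not analysed here.

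Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit on all 6 arrays, eBayes with a trend on signal), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Means are arithmetic, folds come from the fitted log2 change, and standard errors are the moderated ones of limma. Comparisons, tests, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those said to be later. Named genes were the 10 that rose most and the 10 that fell most against vehicle (5 and 5 between the treatments) among called genes whose 2 arrays of one group all lay on one side of those of the other, and up to 4 members of smallest p per list. Genes named outside the rule are said to be so.

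There were 25 gene lists, written from general knowledge, with 741 members, of which 738 were distinct, 687 were on the array and 568 were tested. They covered the renin-angiotensin system, regulators of the renin promoter, cAMP and PKA signalling, NF-kappaB targets and feedback, chemokines and cytokines, interleukin-1 receptor signalling, JAK-STAT3 and acute-phase genes, and interferon response and antigen presentation. Others covered NRF2 and antioxidant defence, p53 targets, ATF4 and endoplasmic reticulum stress, heat shock proteins, immediate-early genes, mitotic genes, DNA replication genes, cholesterol synthesis, oxidative phosphorylation, and glycolysis and hypoxia-induced genes. The rest were extracellular matrix, matrix proteases and their inhibitors, smooth muscle and pericyte genes, TGF-beta targets, and markers of endothelial cells, of leukocytes and macrophages, and of epithelial and tubule cells. The 24 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. List tests between the treatments were added after the data had been seen.

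The changes under both treatments were compared by Pearson and Spearman correlation and covariance, beside 100 simulations of unchanged groups against the same vehicle arrays, and beside the overlap of independent lists. Alternatives were quantile normalization, centring on the 75th percentile, a pseudocount of 32, no filter or a stricter one, other variance models, 4 arrays only, a replicate block, leaving out each array, leaving out probe sets that can match several transcripts, 1 probe set per gene, and a fold of at least 2.

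The steps were tested on simulated data of the same size as interleukin against vehicle, with 22519 probe sets. Of 50 probe sets changed at each log2 size of 0.5, 1, 2 and 3, limma recovered 5, 26, 44 and 47 (10%, 52%, 88% and 94%), with mean fitted sizes of 0.47, 1.03, 1.93 and 2.99. There were 6 false calls, 4.69% of those called, and 0 calls in an unchanged comparison. Camera called 2 of 100 unchanged lists at an unadjusted p under 0.05 and 20 of 20 lists of 30 genes shifted by 0.4. The simulated probe sets varied independently of each other, whereas the estimated correlation in the real lists reached 0.439 (interferon response and antigen presentation). The false rate of the simulated lists therefore does not carry over to correlated lists. The limit first set for this test, more than 90% recovery at a log2 size of 2, was missed at 88%, and the test was then judged instead on direction, fitted size and false calls, a change made after its result was seen. With 2 arrays per group the number of arrays limits the precision, and of the simulated changes of 2-fold 52% were recovered.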

Results

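Gene expression was measured in As4.1 cells, a mouse line studied for renin. The cells received vehicle, hydrogen peroxide, which is a reactive oxygen species, or an interleukin that the labels do not specify further. Each of the 3 groups held 2 separate cultures, and the RNA of each culture was hybridised to 1 Affymetrix mouse array, giving 6 arrays. Signals are MAS5 values on a linear scale, with the same trimmed mean of 1500.01 on each array, and the median signal of an array lay between 192.2 and 232.3. Arrays of 1 group correlated at 0.987 for vehicle, 0.984 for hydrogen peroxide and 0.981 for interleukin, and arrays of different groups at 0.9535 to 0.9753. The first principal component held 48.2% of the variance, with the interleukin arrays at one end and the vehicle arrays at the other. The second held 22.9%, with the hydrogen peroxide arrays apart from the rest. The ratio of the 3' to the 5' beta-actin control probe sets, a measure of RNA integrity and labelling, was 1.22 and 1.26 on the vehicle arrays, 1.35 and 1.32 on the hydrogen peroxide arrays, and 1.46 and 1.55 on the interleukin arrays. The same ratio of the Tfrc controls was 1.85 and 2.14, 3.54 and 2.30, and 3.05 and 3.95, that of the Pcx controls 1.66 and 1.59, 2.89 and 2.03, and 2.30 and 2.46. For the Gapdh controls it was 0.825 to 0.873 over all arrays. Levels below are means ± SD over 2 arrays, folds are ratios of geometric means with the standard error of the log2 change where given, and with 2 arrays per group the number of arrays limits the precision. Renin itself is not analysed here.

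Interleukin against vehicle addressed how the cytokine changed expression in these cells. Saa3, an acute-phase serum amyloid, rose from 244 ± 11.2 to 77335 ± 6505, a log2 change of 8.31 ± 0.13 (SE, n = 2 per group, adjusted p = 1.7e-10). Cxcl5, a chemokine that attracts neutrophils, rose from 69.6 ± 5.94 to 37926 ± 1892. Lcn2, an iron-binding acute-phase protein, rose from 62.6 ± 33.0 to 8479.6 ± 2072, and the cytokine Il6 from 112 ± 27.4 to 7485 ± 2500.0. The other genes among the 10 that rose most were Cfb, a complement factor (60.3-fold), Kng1, a kininogen (28.2-fold), Abcc3, an export transporter (23.3-fold), Prelp, a matrix proteoglycan (22.2-fold), Gstt4, a glutathione transferase (22.1-fold), and Rgs16, a regulator of G-protein signalling (19.98-fold). The mean vehicle signals of these genes other than Saa3 and Prelp lay below 193.7, the lowest mean signal tested, and no detection call was used, so their folds depend on how dim signals are treated. Single vehicle arrays lay above that level for Kng1 (196.3), Abcc3 (210.9) and Gstt4 (238.1). The 2 vehicle arrays lay far apart for Cfb, Kng1 and Gstt4. Without vehicle array 1 the folds of these 3 genes were 159.9, 9.59 and 72.4, and without vehicle array 2 they were 22.7, 82.9 and 6.75. With 32 added to each signal the fold was 374 for Cxcl5, 91.5 for Lcn2, 51.1 for Il6 and 33.5 for Cfb. It was 17.1 for Kng1, 19.7 for Abcc3, 13.6 for Gstt4 and 14.4 for Rgs16.

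The 10 genes that fell most did so by less. Aqp5, a water channel, fell from 623 ± 23.6 to 102 ± 120.3, the latter a dim signal with 1 array far above the other (adjusted p = 0.0176). Ppargc1b, a coactivator of mitochondrial genes, fell from 624 ± 23.7 to 122 ± 7.64, and the transcription factor Zfp423 from 2122 ± 267 to 418 ± 7.71 (adjusted p = 1e-05). The log2 changes of the others were -2.03 for Tmem255a, -2.01 for the secretogranin Scg2, -1.98 for Frmd4b, -1.97 for Tmem158, -1.97 for the alcohol dehydrogenase Adh1, -1.80 for the urea transporter Slc14a1 and -1.79 for Pla2g7. The mean interleukin signals of Aqp5, Ppargc1b and Adh1 lay below 193.7. With 32 added to each signal their log2 changes were -2.66, -2.09 and -1.80. That of Aqp5 was -1.74 without interleukin array 1 and -5.21 without interleukin array 2. By the rule that selected them, both interleukin arrays lay on the same side of both vehicle arrays in each of these 20 genes.

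**Figure D1:**
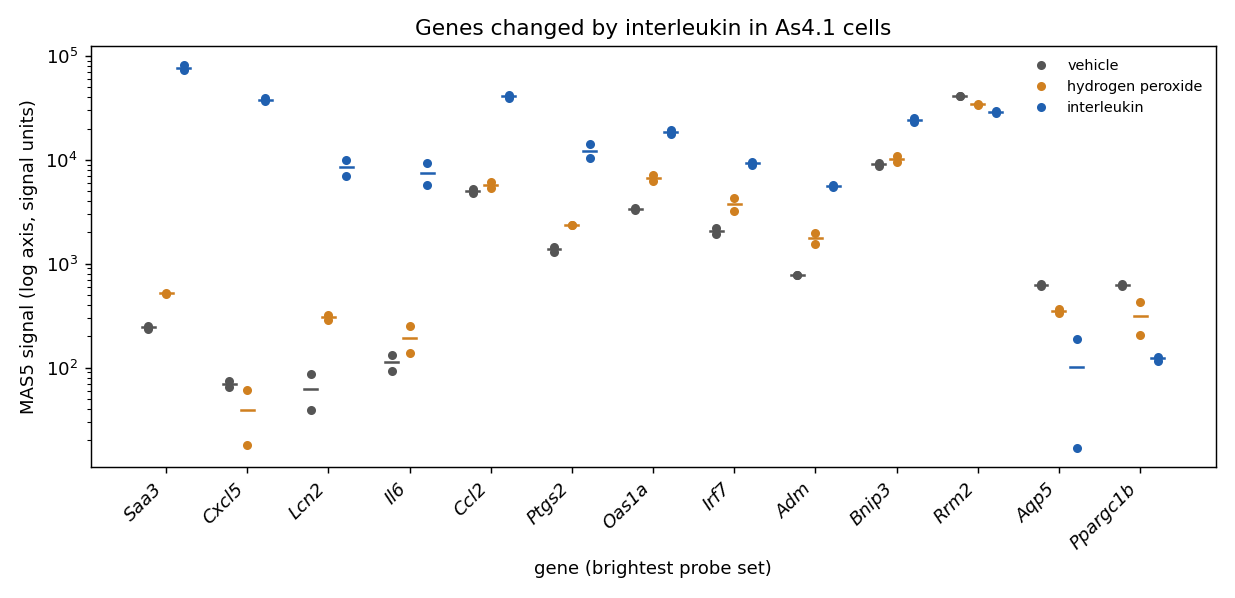
MAS5 signal (log axis, signal units) of 13 genes on each array, with points for single arrays, coloured by group, and short lines for the mean of 2 arrays. Saa3 lies at 244 ± 11.2 on the vehicle arrays and 77335 ± 6505 on the interleukin arrays, while Rrm2 lies at 41293 ± 512 and 28678 ± 934.

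Many inflammatory and interferon genes rose under interleukin. Of 30 tested genes of the interferon response and antigen presentation, 28 rose and 2 did not pass, with 28 risen when adjusted over the list alone (camera adjusted p = 1.9e-26, and adjusted p = 0.149 with an estimated correlation). Examples were Oas1a, an antiviral oligoadenylate synthetase, at 3394 ± 99.6 and 18698 ± 1295, the interferon-induced GTPase Igtp (4.89-fold) and the transcription factor Irf7 (4.48-fold). Among 22 chemokines and cytokines 18 rose and 4 did not pass, with 19 risen when adjusted over the list alone (adjusted p = 1.13e-18, and adjusted p = 0.0965 with an estimated correlation). The monocyte attractants Ccl2 and Ccl7 went from 5024 ± 339 to 41235 ± 1946 and from 4992 ± 370.4 to 27329 ± 3133. NF-kappaB targets and feedback genes rose in 15 of 24 cases and 9 did not pass, with 18 risen when adjusted over the list alone (adjusted p = 1.1e-12, and adjusted p = 0.0835 with an estimated correlation). They included Sod2, the mitochondrial superoxide dismutase (5.08-fold), Nfkbiz, an atypical inhibitor of NF-kappaB (6.58-fold), and the prostaglandin synthase Ptgs2 (8.79-fold). Of 2 other probe sets of Nfkbiz, 1 rose by 2.83 (log2) and 1 did not pass (-0.20, adjusted p = 0.565). JAK-STAT3 and acute-phase genes numbered 20, of which 8 rose, 1 fell and 11 did not pass, or 12 and 1 when adjusted over the list alone (adjusted p = 4.04e-09, and adjusted p = 0.0835 with an estimated correlation). Besides Saa3 and Lcn2, the transcription factor Cebpd rose 9.002-fold and the pentraxin Ptx3 19.6-fold.

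Most tested genes of glycolysis and the hypoxia response rose under interleukin, as did some p53 targets, matrix genes and immediate-early genes. In the glycolysis and hypoxia list 22 of 29 genes rose, 1 fell and 6 did not pass, or 24 and 1 when adjusted over the list alone (adjusted p = 1.73e-13, and adjusted p = 0.124 with an estimated correlation). Adm, which encodes adrenomedullin, rose from 773 ± 2.90 to 5602 ± 151, Bnip3 2.67-fold and Pdk1, a kinase that inhibits pyruvate dehydrogenase, 2.35-fold. Of 27 p53 targets 9 rose, 1 fell and 17 did not pass, or 11 and 1 when adjusted over the list alone (adjusted p = 0.000479, and adjusted p = 0.168 with an estimated correlation). Dram1, a regulator of autophagy, rose 5.19-fold, the death receptor Fas 5.11-fold and the cell cycle inhibitor Cdkn1a 2.39-fold. Extracellular matrix genes rose in 12 and fell in 2 of 27 cases, 13 did not pass, and the counts were 12 and 4 when adjusted over the list alone (adjusted p = 0.00332, and adjusted p = 0.394 with an estimated correlation). Decorin (Dcn) went from 3975 ± 99.6 to 16054 ± 1940.0 and tenascin C (Tnc) from 312 ± 34.8 to 3241 ± 918. Among 27 immediate-early genes 7 rose, 1 fell and 19 did not pass, or 9 and 1 when adjusted over the list alone (adjusted p = 0.0275, and adjusted p = 0.168 with an estimated correlation). The transcription factor Junb rose 2.93-fold, whereas Klf4 fell by 0.96 ± 0.09 (log2, SE).

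Many proliferation genes fell under interleukin. Mitotic genes fell in 18 of 29 cases and 11 did not pass, with 22 fallen when adjusted over the list alone (adjusted p = 2.68e-13, and adjusted p = 0.143 with an estimated correlation). Kif20a, a kinesin of cytokinesis, went from 11715 ± 74.0 to 6843 ± 341 and the spindle protein Nusap1 from 13019 ± 62.1 to 9059.7 ± 53.5. A dimmer probe set of Nusap1 did not pass (log2 0.21, adjusted p = 0.674). Of 32 DNA replication genes 18 fell and 14 did not pass, with 20 fallen when adjusted over the list alone (adjusted p = 9.55e-13, and adjusted p = 0.143 with an estimated correlation). The ribonucleotide reductase subunits Rrm1 and Rrm2 fell by 0.98 ± 0.12 and 0.53 ± 0.07 (log2, SE). In the cAMP and PKA list, whose pathway stimulates renin, 1 gene rose and 6 of 23 fell, 16 did not pass, and the counts were 2 and 9 when adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.168 with an estimated correlation). The phosphodiesterases Pde4d and Pde3b, which break down cAMP, fell by 0.99 and 1.01 (log2), and Pkig, an inhibitor of the kinase PKA, rose 2.35-fold. Without interleukin array 2 the cAMP list had adjusted p = 0.0711. The 46 oxidative phosphorylation genes had a median log2 change of -0.12, and 2 fell, 44 did not pass and 0 passed when adjusted over the list alone (adjusted p = 0.000344, adjusted p = 0.480 with an estimated correlation, and 0.182 by fry). Alongside these lower groups the 3'/5' ratio on the interleukin arrays was 1.46 and 1.55 for beta-actin (1.22 and 1.26 with vehicle), 3.05 and 3.95 for Tfrc (1.85 and 2.14), 2.30 and 2.46 for Pcx (1.66 and 1.59), and 0.847 and 0.873 for Gapdh (0.825 and 0.836).

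Leukocyte and macrophage markers, included for cells of another type, had 2 of 6 tested members risen, 4 not passing and 2 risen when adjusted over the list alone (adjusted p = 0.0458, and adjusted p = 0.229 with an estimated correlation). The members that rose were Cd14, a lipopolysaccharide co-receptor, from 2595 ± 45.4 to 4885 ± 750.2, and Cd68, a lysosomal glycoprotein, from 389 ± 48.9 to 955 ± 349.5. Cd68 had adjusted p = 0.0691 without vehicle array 1 and 0.0565 without interleukin array 1. The list had adjusted p = 0.0657 without vehicle array 2, 0.0515 without hydrogen peroxide array 1, 0.0548 without interleukin array 2 and 0.0543 in a fit of the 4 arrays of these groups only. Endothelial markers had 1 of 5 tested members fallen and 1 when adjusted over the list alone, with a median log2 change of 0.24 and a camera test that pointed lower (adjusted p = 0.830). Of the epithelial and tubule markers only Epcam and Aqp2 were bright enough to be tested, at 570.5 ± 110.2 and 235 ± 70.8 with vehicle and 411 ± 20.9 and 205 ± 61.3 with interleukin, and neither passed.

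Further lists did not pass as groups but held changed members. Of 34 NRF2 and antioxidant genes 8 rose and 2 fell, the same numbers as when adjusted over the list alone (adjusted p = 0.0717), and the metallothionein Mt2 rose 15.1-fold. That list passed after quantile normalization (adjusted p = 0.0465), with a stricter filter on signal (0.0380) and by fry (0.00438). TGF-beta targets rose in 9 and fell in 5 of 22 cases, also when adjusted over the list alone (adjusted p = 0.205), with Ccn2, a matricellular growth factor, up 6.78-fold and Tgfb3 down by 0.92 (log2). The TGF-beta list passed without probe sets that can match several transcripts (adjusted p = 0.0343) and by fry (0.0130). Matrix proteases and their inhibitors rose in 6 and fell in 1 of 17 cases, also when adjusted over the list alone (adjusted p = 0.0509). That list passed without vehicle array 2 (adjusted p = 0.0241), hydrogen peroxide array 2 (0.0482) or interleukin array 1 (0.0426), and by fry (0.0118). It also passed after quantile normalization (0.0465), after 75th percentile centring (0.0489), with no filter on signal (0.0210), without a trend on signal (0.0397) and with 4 arrays only (0.0450). Timp1, a protease inhibitor, rose 2.14-fold, while Timp2 fell by 0.75 (log2). Smooth muscle and pericyte genes rose in 7 and fell in 3 of 22 cases, also when adjusted over the list alone (adjusted p = 0.425), with Acta2, smooth muscle actin, up 1.99-fold. Regulators of the renin promoter numbered 27, of which 4 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.212), and the vitamin D receptor Vdr fell by 0.86 ± 0.12 (log2, SE). The renin-angiotensin list had 1 of 7 tested members fallen, also when adjusted over the list alone, with a positive median (0.09) and a test that pointed lower (adjusted p = 0.616). The member that fell was Enpep, the aminopeptidase that cleaves angiotensin II, at 6106 ± 65.0 and 4092 ± 312, with adjusted p = 0.0553 without vehicle array 1.

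Interleukin-1 receptor signalling genes had 1 of 18 risen, also when adjusted over the list alone (adjusted p = 0.205, and 0.0118 by fry), namely the negative regulator Irak3 at 1.896-fold. Another tested probe set of Irak3 changed by only 0.046 (log2). ATF4 and endoplasmic reticulum stress genes had 4 risen and 1 fallen of 32, also when adjusted over the list alone (adjusted p = 0.186, and 0.0111 without interleukin array 2). Heat shock proteins had 1 risen and 3 fallen of 22, or 1 and 4 when adjusted over the list alone (adjusted p = 0.235). Cholesterol synthesis genes had 2 risen and 1 fallen of 20, also when adjusted over the list alone, with a median near 0 (0.01) and a test that pointed lower (adjusted p = 0.803). Over all probe sets, limma called 3627 of 22519 with interleukin, 1708 higher and 1919 lower, of which 584 and 456 differed at least 2-fold. By the brightest probe set of each gene 1065 genes were higher and 720 lower. Leaving out an array of a compared group leaves 1 array there, which by itself lowers the power to call. The count and its split depended on the vehicle arrays and on the variance model, with 891 higher and 672 lower of 1563 without vehicle array 1, 931 and 655 of 1586 without vehicle array 2, and 1003 and 780 of 1783 when the variance was modelled without a trend on signal. With 1 probe set per gene 2128 were called of 10892 tested. Without interleukin array 2 the numbers were 1471 higher and 1466 lower. With an estimated correlation between genes camera passed 0 of 24 lists, 7 at an unadjusted p under 0.05, and the self-contained test fry passed 16.

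**Figure D2:**
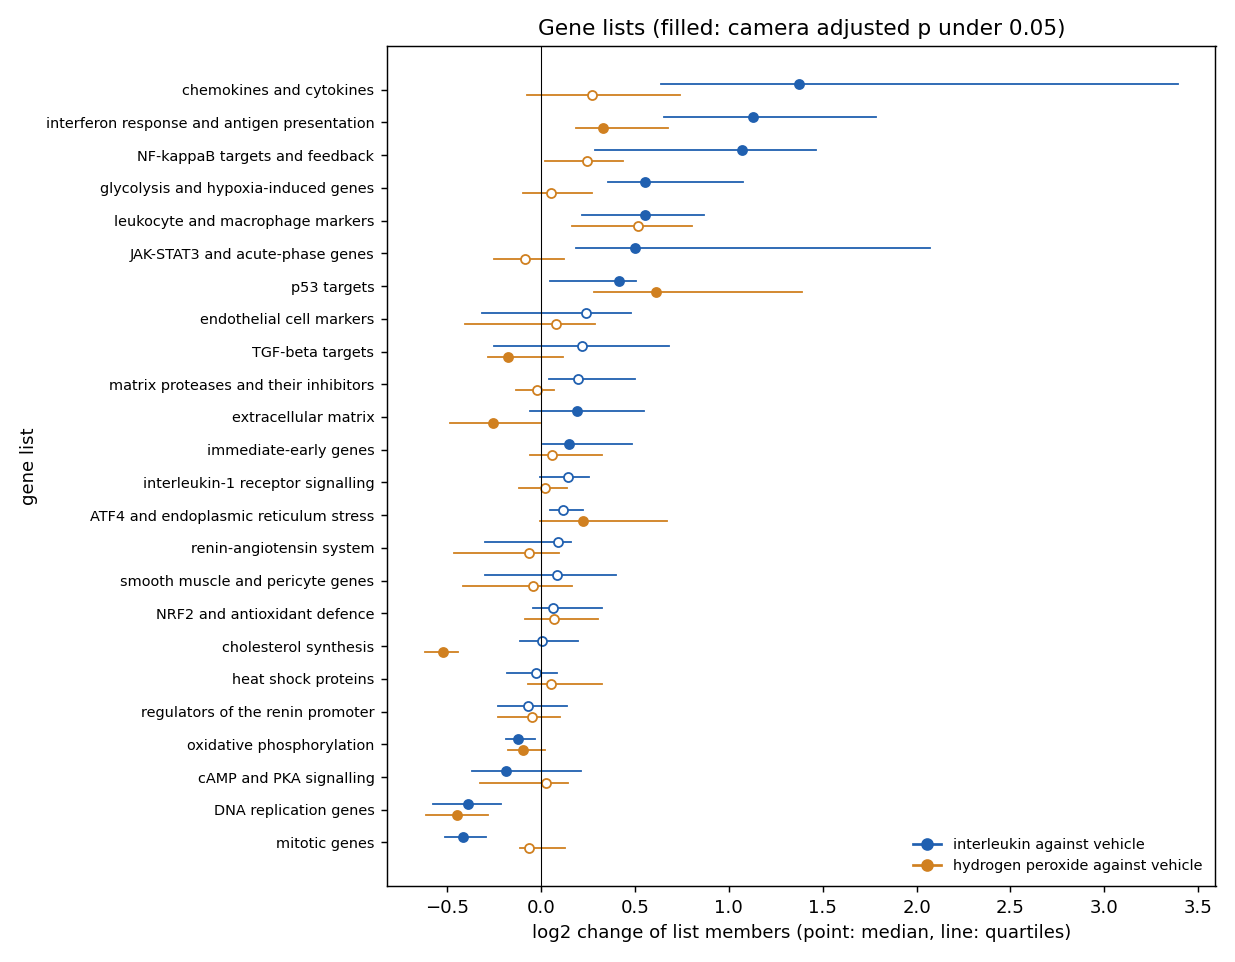
Median log2 change (points) and quartiles (lines) of the tested members of 24 gene lists under interleukin and under hydrogen peroxide, each against vehicle, with filled points for lists that passed camera. The interferon list lies at 1.13 under interleukin and 0.33 under hydrogen peroxide, and the cholesterol synthesis list at 0.01 and -0.52.

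Hydrogen peroxide against vehicle addressed the response to an oxidant. Cdkn1a, the p53-induced cell cycle inhibitor, rose from 2551 ± 6.29 to 13569 ± 319.8, a log2 change of 2.41 ± 0.10 (SE, n = 2 per group, adjusted p = 3.02e-06). Dcxr, a xylulose reductase, rose from 831 ± 51.3 to 5289 ± 232 and Eda2r, a receptor of the tumour necrosis factor family, from 290.1 ± 16.0 to 1556 ± 41.1. The mitochondrial protein Chchd10 rose 6.78-fold, the RNA-binding protein Celf5 5.37-fold and Car6, a secreted carbonic anhydrase, 13.2-fold. Folds from dim vehicle signals, below 193.7, were among the highest, in Anxa8 (85.0 ± 77.4 to 1182 ± 12.5), 1700007K13Rik (95.0 ± 9.33 to 1573 ± 146), P2rx3 (89.9 ± 53.3 to 789 ± 143) and Atg9b (85.5 ± 20.4 to 701 ± 158), of which P2rx3 had adjusted p = 0.0714 without vehicle array 1. With 32 added to each signal the fold was 11.7 for Anxa8, 12.6 for 1700007K13Rik, 7.03 for P2rx3 and 6.21 for Atg9b. Without vehicle array 1 the fold was 8.46 for Anxa8, 6.14 for P2rx3 and 8.10 for Celf5, and without vehicle array 2 it was 39.0, 15.0 and 3.56. The potassium channel Kcnj8 fell from 2366 ± 55.5 to 761 ± 126, and Prss35, Tmem255a, the chemokine Cxcl13 and the calcification inhibitor Mgp fell by 1.58, 1.56, 1.53 and 1.34 (log2). Another probe set of Cxcl13 fell by 1.34. The other genes among the 10 that fell most were S100g, Mfsd2a, A2m, Stc1 and Mturn, with log2 changes of -1.58, -1.49, -1.47, -1.40 and -1.34, but these 5 lost their calls when single arrays were left out. The mean hydrogen peroxide signal of Mfsd2a lay below 193.7, and with 32 added its log2 change was -1.34. Without vehicle array 1 the adjusted p was 0.105, 0.216, 0.0590, 0.104 and 0.0707. Without vehicle array 2 it was 0.209 for Mfsd2a, 0.104 for A2m, 0.103 for Stc1 and 0.0935 for Mturn. Without hydrogen peroxide array 1 it was 0.169 for Mfsd2a, 0.0726 for A2m, 0.0577 for Stc1 and 0.0626 for Mturn, and without hydrogen peroxide array 2 it was 0.0615 for S100g, 0.0746 for Mfsd2a and 0.0713 for Stc1.

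**Figure D3:**
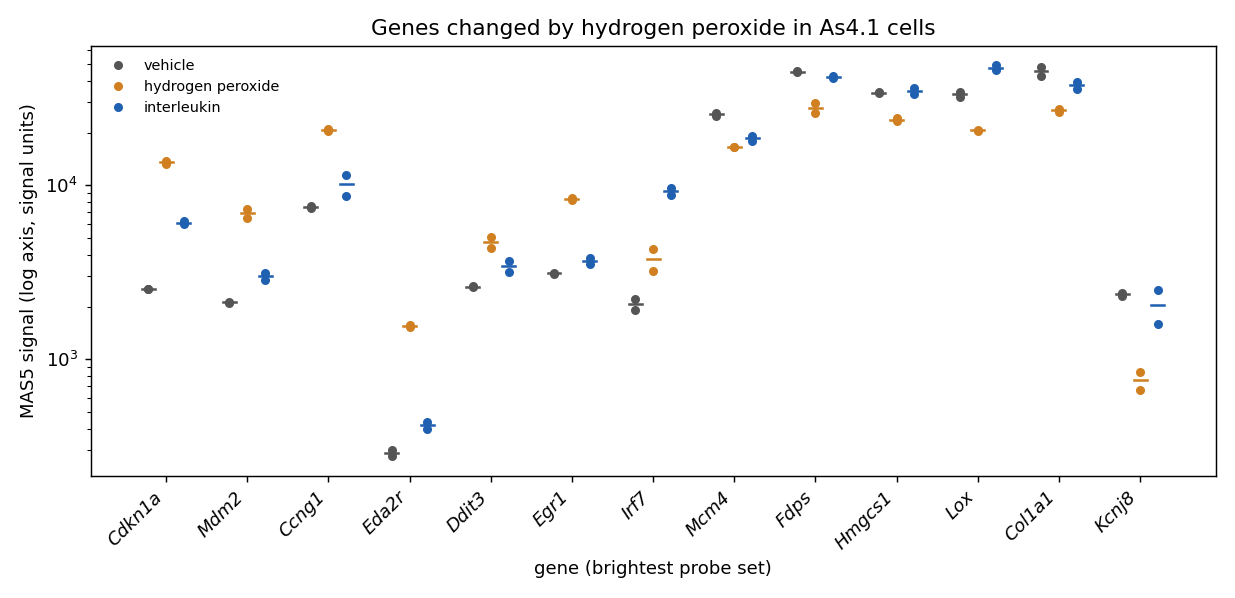
MAS5 signal (log axis, signal units) of 13 genes on each array, with points for single arrays, coloured by group, and short lines for the mean of 2 arrays. Cdkn1a lies at 2551 ± 6.29 with vehicle and 13569 ± 319.8 with hydrogen peroxide, and Fdps at 44953 ± 322 and 27868 ± 2479.

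The p53 targets rose with hydrogen peroxide in 13 of 27 cases and 14 did not pass, and 16 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.18e-11, and adjusted p = 0.177 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, rose 3.23-fold, Trp53inp1 3.54-fold and the cyclin Ccng1 2.75-fold. DNA replication genes fell in 19 of 32 cases and 13 did not pass, with 25 fallen when adjusted over the list alone (adjusted p = 2.38e-21, and adjusted p = 0.177 with an estimated correlation). Mcm4, a subunit of the replicative helicase, went from 25645 ± 768 to 16585 ± 86.4 and the clamp loader subunit Rfc3 from 8073 ± 557 to 4648 ± 100.4. Mitotic genes did not pass as a group under hydrogen peroxide (adjusted p = 0.287), with 1 risen and 2 fallen of 29, also when adjusted over the list alone. Of 20 cholesterol synthesis genes 13 fell and 7 did not pass, with 19 fallen when adjusted over the list alone (adjusted p = 3.93e-17, and adjusted p = 0.222 with an estimated correlation). Fdps, the farnesyl diphosphate synthase, went from 44953 ± 322 to 27868 ± 2479 and the isomerase Idi1 from 26951 ± 1263 to 16706 ± 1517. Extracellular matrix genes fell in 7 of 27 cases and 20 did not pass, and 4 rose and 15 fell when adjusted over the list alone (adjusted p = 2.75e-07, and adjusted p = 0.349 with an estimated correlation). The collagens Col1a1 and Col3a1 fell by 0.74 ± 0.08 and 0.70 ± 0.09 (log2, SE), and the collagen cross-linking enzyme Lox by 0.69 ± 0.07. Another probe set of Lox fell by 0.88, and a dim one did not pass (log2 0.50, adjusted p = 0.594). Alongside these lower groups the 3'/5' ratio on the hydrogen peroxide arrays was 1.35 and 1.32 for beta-actin (1.22 and 1.26 with vehicle), 3.54 and 2.30 for Tfrc (1.85 and 2.14), 2.89 and 2.03 for Pcx (1.66 and 1.59), and 0.844 and 0.836 for Gapdh (0.825 and 0.836).

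Interferon response genes rose with hydrogen peroxide in 11 of 30 cases and 19 did not pass, with 20 risen when adjusted over the list alone (adjusted p = 6.43e-09, and adjusted p = 0.349 with an estimated correlation). Oas1a went from 3394 ± 99.6 to 6716 ± 601 and the transcription factor Irf9 from 1571 ± 73.9 to 3665 ± 214. Of 32 ATF4 and endoplasmic reticulum stress genes 10 rose, 1 fell and 21 did not pass, or 12 and 1 when adjusted over the list alone (adjusted p = 0.00177, and adjusted p = 0.349 with an estimated correlation). Asns, the asparagine synthetase, rose from 3844 ± 268 to 11943 ± 1126, with adjusted p = 0.0554 without vehicle array 1, and the amino acid transporter Slc7a5 rose 1.93-fold, with adjusted p = 0.0847 without that array. Oxidative phosphorylation genes had a median log2 change of -0.09, and 2 of 46 fell, 44 did not pass and 2 fell when adjusted over the list alone (adjusted p = 0.000405, and adjusted p = 0.504 with an estimated correlation). That list had adjusted p = 0.11 without hydrogen peroxide array 2, 0.15 after quantile normalization and 0.267 by fry. Among 22 TGF-beta targets 1 rose, 1 fell and 20 did not pass, or 2 and 4 when adjusted over the list alone (adjusted p = 0.0264, and adjusted p = 0.349 with an estimated correlation). That list, whose median log2 change was -0.17, had adjusted p = 0.113 without vehicle array 1, 0.123 without hydrogen peroxide array 2 and 0.125 by fry.

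NRF2 and antioxidant genes, the classical oxidant response, did not pass as a group with hydrogen peroxide (adjusted p = 0.439), and 2 rose, 2 fell and 30 of 34 did not pass, or 5 and 2 when adjusted over the list alone. By fry that list passed (adjusted p = 0.0235). Ephx1, an epoxide hydrolase, rose from 1574 ± 31.2 to 6789 ± 358. Immediate-early genes did not pass as a group (adjusted p = 0.167), with 6 risen and 1 fallen of 27, also when adjusted over the list alone, and the transcription factors Egr1 and Egr3 rose 2.67-fold and 3.41-fold. The immediate-early list passed with no filter on signal (adjusted p = 0.0398) and by fry (0.00532). Heat shock proteins had 2 of 22 risen, or 6 when adjusted over the list alone (adjusted p = 0.226), among them the small heat shock protein Cryab at 1.99-fold. They passed as a group after quantile normalization (adjusted p = 0.0397) and by fry (0.0235). NF-kappaB targets had 3 of 24 risen, or 7 risen and 1 fallen when adjusted over the list alone (adjusted p = 0.0788), with the hyaluronan receptor Cd44 up 1.605-fold. The NF-kappaB list passed without vehicle array 1 (adjusted p = 0.0345), with a stricter filter on signal (0.0399), without probe sets that can match several transcripts (0.0184) and by fry (0.0365). Chemokines and cytokines had 1 risen and 2 fallen of 22, or 6 and 3 when adjusted over the list alone (adjusted p = 0.300). In the JAK-STAT3 and acute-phase list 3 rose and 1 fell of 20, or 3 and 3 when adjusted over the list alone, with a negative median (-0.09), a positive mean (0.16) and a test that pointed lower (adjusted p = 0.461), and Ptx3 rose 2.995-fold. Smooth muscle and pericyte genes had 1 risen and 4 fallen of 22, or 5 and 6 when adjusted over the list alone (adjusted p = 0.181), with the receptor Notch3 up 2.84-fold.

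The remaining lists did not pass with hydrogen peroxide either. Glycolysis and hypoxia genes had 3 risen and 1 fallen of 29, or 5 and 1 when adjusted over the list alone (adjusted p = 0.541), with Adm at 2.27-fold. The cAMP and PKA list had 4 of 23 fallen, or 5 when adjusted over the list alone, with a positive median (0.03) and a test that pointed lower (adjusted p = 0.107, and 0.0368 by fry). Regulators of the renin promoter had 2 of 27 fallen, or 3 risen and 2 fallen when adjusted over the list alone (adjusted p = 0.151). In the renin-angiotensin list 1 of 7 fell, or 2 when adjusted over the list alone (adjusted p = 0.151), namely Enpep from 6106 ± 65.0 to 3808 ± 69.7, whose adjusted p was 0.0739 without vehicle array 1 and 0.0681 without vehicle array 2. Matrix proteases and their inhibitors had 1 risen and 1 fallen of 17, also when adjusted over the list alone (adjusted p = 0.226), with Timp2 down by 0.54 (log2). Interleukin-1 receptor signalling genes had 2 of 18 fallen, or 2 risen and 2 fallen when adjusted over the list alone, with a positive median (0.02) and a test that pointed lower (adjusted p = 0.505). Leukocyte and macrophage markers had 1 of 6 risen, or 3 when adjusted over the list alone (adjusted p = 0.133, and 0.00532 by fry). Endothelial markers had 0 risen and 0 fallen of 5, or 1 and 1 when adjusted over the list alone, with a positive median (0.08) and a test that pointed lower (adjusted p = 0.575). Epcam and Aqp2, the tested epithelial markers, were at 329.6 ± 28.2 and 314 ± 27.7 and did not pass, though 1 of them fell when adjusted over the list alone.

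Over all probe sets limma called 1282 of 22519 with hydrogen peroxide, 686 higher and 596 lower (53.5% higher, and 40.7% higher with arrays centred on their 75th percentile), of which 198 and 93 differed at least 2-fold. By the brightest probe set of each gene 444 genes were higher and 317 lower. Leaving out an array of a compared group leaves 1 array there, which by itself lowers the power to call. The count of 1282 probe sets varied with the arrays kept, the variance model, the filter on signal and the choice of probe sets. It was 242 without vehicle array 1, 264 without vehicle array 2, 388 without hydrogen peroxide array 1 (168 higher, 220 lower), 671 without hydrogen peroxide array 2 (242 higher, 429 lower), and 57 when the variance was modelled without a trend on signal. It was 762 with no filter on signal, where more probe sets were adjusted over, and 825 without probe sets that can match several transcripts, where fewer were tested. With an estimated correlation camera passed 0 of 24 lists, 3 at an unadjusted p under 0.05, and fry passed 12.

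Interleukin against hydrogen peroxide addressed which genes separated both treatments. Saa3 was higher with interleukin by 7.22 ± 0.13 (log2, SE, n = 2 per group, adjusted p = 7.31e-10), at 77335 ± 6505 against 517 ± 13.7. Cxcl5, Il6, Lcn2 and Abcc3 were the others of the 5 genes that were higher by most, with log2 differences of 10.17, 5.29, 4.78 and 4.52. The mean hydrogen peroxide signals of Cxcl5 and Abcc3 lay below 193.7 and that of Il6 at 194.2, with no detection call used. With 32 added to each signal the log2 differences of these 4 genes were 9.13, 5.06, 4.64 and 4.29. That of Cxcl5 was 9.30 without hydrogen peroxide array 1 and 11.04 without hydrogen peroxide array 2. Lower with interleukin by most were Car6 (2859 ± 274 with hydrogen peroxide and 239.8 ± 206 with interleukin), the actin-binding protein Avil (1122 ± 358 and 193 ± 194), the growth cone protein Gap43 (739 ± 113 and 142 ± 48.2), 1700007K13Rik (1573 ± 146 and 303 ± 14.0) and Scg2 (1480.2 ± 110.5 and 288 ± 45.8). The mean interleukin signals of Avil and Gap43 lay below 193.7, with Avil at 56.4 and 330.0 on the single arrays. With 32 added their log2 differences were -2.65 and -2.17. Without interleukin array 1 the log2 differences of Car6 and Avil were -4.92 and -1.73, and without interleukin array 2 they were -2.89 and -4.28. Avil had adjusted p = 0.117 without hydrogen peroxide array 2.

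Lists that were tested on this contrast only after the data had been seen also differed. Interferon genes were higher with interleukin in 23 of 30 cases, or 26 when adjusted over the list alone (adjusted p = 3.41e-22, and adjusted p = 0.122 with an estimated correlation). Chemokines and cytokines were higher in 15 of 22, or 16 when adjusted over the list alone (adjusted p = 2.84e-20, and adjusted p = 0.0857 with an estimated correlation). Glycolysis and hypoxia genes were higher in 20 of 29, or 23 with 2 lower when adjusted over the list alone (adjusted p = 6.75e-16, and adjusted p = 0.0984 with an estimated correlation). Extracellular matrix genes were higher in 15 of 27, or 20 when adjusted over the list alone (adjusted p = 5.88e-15, and adjusted p = 0.122 with an estimated correlation), with Lox at 47411 ± 2068 against 20713 ± 306 and Col3a1 at 33796 ± 3119 against 13596 ± 734. Cholesterol synthesis genes were higher in 13 of 20, or 19 when adjusted over the list alone (adjusted p = 6.86e-14, and adjusted p = 0.122 with an estimated correlation), with the sterol dehydrogenase Nsdhl at 15156 ± 1098 against 8059.8 ± 174. JAK-STAT3 and acute-phase genes were higher in 10 of 20, or 13 when adjusted over the list alone (adjusted p = 2.62e-14, and adjusted p = 0.0810 with an estimated correlation). NF-kappaB targets were higher in 10 of 24, or 15 when adjusted over the list alone (adjusted p = 7.64e-12, and adjusted p = 0.0857 with an estimated correlation). Mitotic genes were lower with interleukin in 17 of 29 cases, or 22 when adjusted over the list alone (adjusted p = 6.23e-12, and adjusted p = 0.122 with an estimated correlation), with Kif20a at 6843 ± 341 against 11149 ± 690.4. Of the p53 targets 3 were higher and 11 lower of 27, or 4 and 16 when adjusted over the list alone (adjusted p = 0.000174, and adjusted p = 0.122 with an estimated correlation), with Cdkn1a at 6104 ± 154 against 13569 ± 319.8 and Fas at 3824 ± 421 against 978 ± 211.

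Smaller differences between both treatments passed in 5 more lists. TGF-beta targets were higher with interleukin (adjusted p = 0.000294, and adjusted p = 0.122 with an estimated correlation) in 8 and lower in 2 of 22 cases, or 11 and 2 when adjusted over the list alone. Matrix proteases and their inhibitors were higher in 4 of 17, or 4 with 1 lower when adjusted over the list alone (adjusted p = 0.00120, and adjusted p = 0.149 with an estimated correlation). Heat shock proteins were lower in 5 of 22, or 6 with 1 higher when adjusted over the list alone (adjusted p = 0.00811, and adjusted p = 0.122 with an estimated correlation). Smooth muscle and pericyte genes were higher in 3 of 22, or 5 with 1 lower when adjusted over the list alone (adjusted p = 0.0307, adjusted p = 0.296 with an estimated correlation, 0.182 without interleukin array 1, 0.0626 without probe sets that can match several transcripts and 0.366 with no filter on signal). ATF4 and endoplasmic reticulum stress genes were lower in 3 of 32, also when adjusted over the list alone (adjusted p = 0.0461, and adjusted p = 0.412 with an estimated correlation), and the list had adjusted p = 0.12 without hydrogen peroxide array 2 and 0.405 without interleukin array 2, 0.088 without a trend on signal and 0.102 by fry. It had 0.0704 with a stricter filter on signal and 0.0614 without probe sets that can match several transcripts. DNA replication genes did not pass on this contrast (adjusted p = 0.334), with a median log2 difference of 0.04, 2 higher and 1 lower, or 3 and 2 when adjusted over the list alone. The other lists that did not pass were cAMP and PKA signalling (adjusted p = 0.351, 1 higher and 3 lower, or 1 and 7 when adjusted over the list alone), oxidative phosphorylation (0.675, 1 and 1, or 0 and 0), leukocyte markers (0.525, 1 and 0, or 1 and 0), renin promoter regulators (0.906, 0 and 1, or 0 and 0) and the renin-angiotensin list (0.334, 0 and 0, or 0 and 0). Immediate-early genes (7 higher and 5 lower, or 9 and 5 when adjusted over the list alone), NRF2 genes (5 and 1, or 6 and 5) and endothelial markers (0 and 0) did not pass either (adjusted p = 0.616, 0.593 and 0.903), and the medians were negative (-0.04, -0.04 and -0.05) and the tests pointed higher. Interleukin-1 receptor signalling genes had 2 higher, also when adjusted over the list alone (adjusted p = 0.125, 0.0492 without vehicle array 2 and 0.0244 by fry). Of the lists that did not pass here, cAMP and PKA signalling passed by fry (adjusted p = 0.0140) and without probe sets that can match several transcripts (0.0313). NRF2 genes passed by fry (0.0428) and oxidative phosphorylation after quantile normalization (0.0344). Limma called 1987 of 22519 probe sets between both treatments, 1115 higher and 872 lower with interleukin, of which 417 and 162 differed at least 2-fold. The count was 852 without hydrogen peroxide array 2, its split was 940 higher and 988 lower without interleukin array 1, and the count was 716 when the variance was modelled without a trend on signal. With an estimated correlation camera passed 0 of 24 lists, 8 at an unadjusted p under 0.05, while fry passed 16.

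Changes under both treatments were then set side by side. Of the probe sets called in both, 337 were higher and 320 lower with each treatment, against 52.0 and 50.8 for independent lists of the same sizes. In the opposite directions 39 were higher with interleukin and lower with hydrogen peroxide, against 45.2, and 1 was lower with interleukin and higher with hydrogen peroxide, against 58.5. By gene these were 213, 155, 28 and 1. Both lists of calls rest on the same vehicle arrays and so are not independent. That sharing raises the overlap in the same direction and lowers it in opposite directions. The numbers for independent lists therefore cannot separate a common response from shared vehicle arrays. Among the 28 genes were Slpi, a secreted protease inhibitor, at 1809.5 ± 139.6 with vehicle, 1150.5 ± 213 with hydrogen peroxide and 21441 ± 2625 with interleukin, the chemokine Ccl8 at 6091 ± 367, 2922 ± 843 and 26643 ± 4905, and the matrix genes Lox at 33345 ± 1363, 20713 ± 306 and 47411 ± 2068 and Col3a1 at 22047 ± 1660.0, 13596 ± 734 and 33796 ± 3119. The 1 gene in the other direction was the zinc finger gene Zfp37, at 2804 ± 138, 4075 ± 70.4 and 2072 ± 41.9. A dim probe set of Lox passed in neither comparison (adjusted p = 0.392 and 0.594). Slpi, Ccl8 under interleukin and Zfp37 were picked after their values had been seen. The hydrogen peroxide call of Ccl8 had adjusted p = 0.0733 without vehicle array 1 and 0.0519 without vehicle array 2. The hydrogen peroxide call of Slpi had adjusted p = 0.106 without vehicle array 1, 0.212 without vehicle array 2 and 0.143 without hydrogen peroxide array 2. Zfp37 lost its hydrogen peroxide call without vehicle array 1 (adjusted p = 0.182), vehicle array 2 (0.126), hydrogen peroxide array 1 (0.123) or hydrogen peroxide array 2 (0.112). It lost its interleukin call without vehicle array 1 (adjusted p = 0.110), vehicle array 2 (0.1999), interleukin array 1 (0.0798) or interleukin array 2 (0.0554).

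Across probe sets, which are not independent replicates, the log2 changes of both treatments had a Pearson correlation of 0.562, a Spearman correlation of 0.582 and a covariance of 0.121. Both comparisons share the vehicle arrays, and 100 simulations of unchanged groups against those arrays gave a mean Pearson correlation of 0.499, a covariance of 0.0255 and 0.06 probe sets called in both. Those simulated groups held no changed probe sets, so the 0.06 does not give the overlap that shared arrays produce among changed ones. Both changes had the same sign in 70.9% of probe sets, against 66.7% in those simulations. The covariance exceeded the simulated one by 0.0952, in simulations whose probe sets varied independently of each other. With a different vehicle array for each treatment the correlation was 0.387 and 0.405, and without hydrogen peroxide array 1 it was 0.436.

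**Figure D4:**
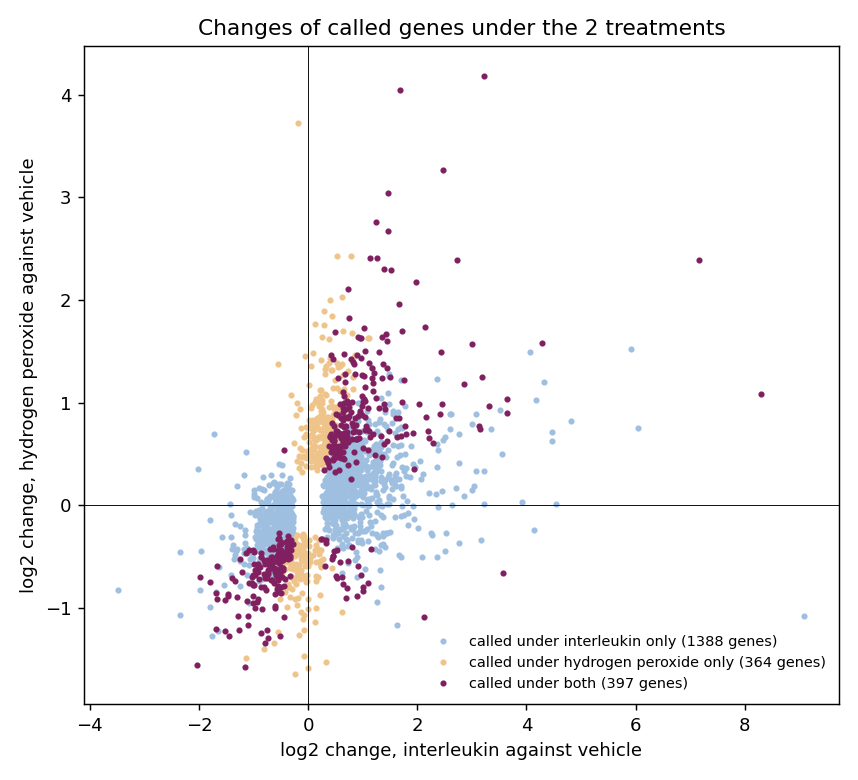
Log2 change under interleukin (horizontal) and under hydrogen peroxide (vertical), each against vehicle, with 1 point per gene called in at least 1 of the comparisons. Of these genes 1388 were called under interleukin alone, 364 under hydrogen peroxide alone and 397 under both, and the last lie mostly in the quadrants where both changes have the same sign.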

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

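The list tests between the treatments and the crossed pairing were tests chosen after the result was seen. Against 3627, 1282 and 1987 probe sets for interleukin against vehicle, hydrogen peroxide against vehicle and interleukin against hydrogen peroxide, quantile normalization, 75th percentile centring, a pseudocount, the robust variance model, 4 arrays only and the stricter signal filter each gave counts within 1.5 times. Without a trend on signal the counts were 1783, 57 and 716, and with a fold of at least 2 they were 1040, 291 and 579. The hydrogen peroxide count was 762 with no signal filter and 825 without probe sets that can match several transcripts, and the interleukin count was 2128 with 1 probe set per gene, where fewer were tested. Apart from the last of these and the fold limit, whose construction lowers a count, the cause was not tested.

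Leaving out 1 array, where the lone array is assumed to vary like the other groups, gave 1563 to 3599, 242 to 1767 and 852 to 1928 probe sets. The interleukin split, 47.1% higher with all arrays, was 57.0% without vehicle array 1 and 58.7% without vehicle array 2, and 56.2% without a trend on signal. The hydrogen peroxide count was lowest without vehicle array 1 (242) and was 264 without vehicle array 2, 388 without hydrogen peroxide array 1 and 671 without hydrogen peroxide array 2. Of 116 genes followed under hydrogen peroxide 89 had a call, and 47, 41, 32 and 27 of these lost it in these 4 cases (1 was not tested in the last), and 77 without a trend on signal. Of 114 followed under interleukin 98 had a call, of which at most 20 lost it on leaving out an array. No named gene and no list that had passed changed direction. With 1 array left in a compared group the power is lower by construction, and its share in the lower counts and lost calls was not tested.

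Outside the estimated correlation, list calls were lost 7, 6 and 10 times and gained 16, 11 and 6 times over these alternatives and fry. Fry gave 4, 6 and 3 of the gains. It asks whether list members change at all, whereas camera asks whether they change more than other genes. A list that passes by fry alone therefore answers another question. Under interleukin the leukocyte list was lost in 5 of them (adjusted p = 0.0543 with 4 arrays only) and oxidative phosphorylation by fry (0.182). Under hydrogen peroxide oxidative phosphorylation was lost after quantile normalization (0.15) and by fry (0.267), and TGF-beta targets by fry (0.125). Between the treatments the ATF4 list was lost in 7 and the smooth muscle list in 3, the latter at 0.366 with no signal filter. Matrix proteases under interleukin, at 0.0509, passed in 9, among them both other normalizations (0.0465 and 0.0489). NRF2 genes under interleukin and heat shock proteins under hydrogen peroxide passed after quantile normalization (0.0465 and 0.0397), and immediate-early genes under hydrogen peroxide with no signal filter (0.0398).

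With an estimated correlation camera passed 0, 0 and 0 of 24 lists (7, 3 and 8 at an unadjusted p under 0.05). Every list call by camera therefore depends on the preset setting. Fry passed 16, 12 and 16. A higher correlation does not account for every loss. Under interleukin the estimates of the JAK-STAT3 list (-0.0306) and the immediate-early list (-0.0315) lay below the preset 0.01. Their adjusted p still rose from 4.04e-09 to 0.0835 and from 0.0275 to 0.168. Other lists had estimates above 0.01, up to 0.439 for the interferon list. The setting with an estimated correlation also rests on the few residual degrees of freedom of these arrays, which by itself raises its p. A call lost under it is therefore not by itself a sign of dependence between genes. The share of each in the lost calls was not tested. The correlation of the 2 sets of changes, 0.562, was 0.3872 and 0.4053 with a different vehicle array per treatment and 0.4362 to 0.6088 leaving out 1 array.

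Cultures of different groups share only a number. Deviations of same-numbered arrays correlated at 0.107, 0.0535 and -0.129. A replicate block gave 3342, 1170 and 1756 probe sets and 12, 8 and 13 lists, with adjusted p = 0.0531 for the leukocyte list under interleukin and 0.0602 for the ATF4 list between the treatments, and it ended no other list call. With numbers crossed on the 4 treated arrays the count was 3313, against 1702 uncrossed. Dim signals limit the folds, since the filter kept signals from 193.7 upward and no background estimate was used.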

Other observations

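The tests of gene families by symbol, of shared vehicle arrays and of carry-over were tests chosen after the result was seen. Camera was run on 167 families of at least 8 genes that share the stem of their symbol. Under interleukin 6 passed: Cxcl chemokines (7 of 8 rose, adjusted p = 4.04e-07), splicing factors of the Srsf family (5 of 9 fell, 0.00209), Haus genes (4 of 8 fell, 0.00209), genes whose symbols start with Mcm (4 of 10 fell, 0.00259), Ifi interferon-induced genes (5 of 9 rose, 0.00659) and Parp genes (5 of 11 rose and Parp1 fell, 0.025). The Srsf, Haus and Parp families have 0 members in the fixed lists. All had adjusted p = 0.964 with an estimated correlation. That setting rests on the few residual degrees of freedom of 6 arrays in 3 groups. Over 167 families it could hardly pass any, here or in the comparisons below, so its values say little about dependence between genes.

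Under hydrogen peroxide 2 families passed, Mcm (5 of 10 fell, adjusted p = 0.000108) and Col collagens (4 of 22 fell and Col18a1 rose, 0.000109), with adjusted p = 0.977 with an estimated correlation. Between the treatments 6 passed: Cxcl (8 of 8 higher with interleukin, adjusted p = 2.69e-12), Adamts (5 of 9 higher, 0.000172), Col (9 of 22 higher and 2 lower, 0.00105), Ifi (5 of 9 higher and 1 lower, 0.0441), Polr (1 of 24 lower, 0.0441) and Rbm (1 of 30 lower, 0.0441). Polr and Rbm pointed lower and passed under neither treatment. The families had adjusted p = 0.692 (Cxcl) or 0.976 with an estimated correlation.

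Interleukin lowered more probe sets than it raised (1708 higher, 1919 lower) while raising more genes by their brightest probe set, but this split turned over without either vehicle array (891 and 672, 931 and 655), so the pattern itself is uncertain. A 3' bias of the labelled RNA may contribute: second probe sets changed by a median of -0.08395 (interval -0.0945 to -0.0741) relative to the brightest of their gene, chosen on arrays outside the comparison after a first version had given -0.0820, and by -0.0667 under hydrogen peroxide (-0.0756 to -0.0601). These intervals come from resampling probe sets, which are not independent replicates, and hold no variation between cultures. They overlap, so the order of the treatments is not used here. With all arrays hydrogen peroxide gave 686 higher and 596 lower probe sets, a split that also changed with the processing. Such a gap therefore also occurred without more probe sets lowered than raised. The Tfrc ratios (3.54 and 2.30 with hydrogen peroxide, 3.05 and 3.95 with interleukin) and the Pcx ratios (2.89 and 2.03, 2.30 and 2.46) overlap between the treatments and lie above those with vehicle (1.85 and 2.14, 1.66 and 1.59), and the Gapdh ratio lay at 0.825 to 0.873 throughout. A shift that depends on signal alone is argued against on these arrays, since signal-matched genes with 1 tested probe set lay 0.1686 above second probe sets. The interval of 0.156 to 0.182 again comes from resampling probe sets and not cultures. Such a probe set is the brightest tested one of its gene, so the groups differ in more than signal. Alternative or unspliced transcripts stay open, as does a biological cause, which was not tested.

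The changes under both treatments had the same sign in 70.9% of probe sets, against 66.7% in simulated unchanged groups sharing the vehicle arrays, so the direction alone says little. Shared vehicle arrays whose noise is independent between probe sets are argued against as the whole cause by a covariance of 0.1206, above the highest simulated one at 0.0273. The simulated probe sets varied independently. A deviation of the vehicle arrays shared by many probe sets is therefore not covered by this range or by the simulated one below. A bias confined to dim probe sets as the whole cause is argued against by the brightest 1 of 3 equal parts of the probe sets, where the covariance was 0.05656 and the highest simulated one 0.00762. The excess over the simulated covariance grew as signal fell, at 0.0496 in the brightest part, 0.0903 in the middle and 0.145 in the dimmest. A bias that weakens with signal but reaches bright probe sets is not excluded by this. Both treatments also raised the beta-actin 3'/5' ratio (1.22 and 1.26 with vehicle, 1.35 and 1.32, 1.46 and 1.55) and shifted second probe sets down (-0.0667 and -0.08395). The share of this in the covariance was not tested, so a common bias and a common response both stay open.

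Of 30 interferon genes 11 rose under hydrogen peroxide (camera adjusted p = 6.43e-09, and adjusted p = 0.349 with an estimated correlation). Carry-over of RNA from the interleukin cultures is argued against, since 9 abundant induced transcripts showed a median 0.3544% of their interleukin rise (-3.36% to 10.6%) against 24.2% for the interferon genes, with a lower quartile of 12.8%. The median shift of the list was 0.331, and the median difference between the 2 arrays of a group was 0.0172 for vehicle, 0.0820 for hydrogen peroxide and 0.230 for interleukin, which is not part of this comparison. The bound set beforehand used the largest of these, which the shift exceeded 1.44 times where more than 2 was required, so variation between cultures cannot be told apart from an effect of hydrogen peroxide by that test, although the 2 groups compared differed less within themselves. With 2 cultures per group it stays open.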
